A study of Mus musculus with 12 samples.

How the data were processed

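The series holds 12 bulk RNA libraries of mouse lung fibroblasts in 4 groups of 3: 2 subgroups, abbreviated MF and MyoF in the labels, each from normal mice (N) and from mice with lung metastasis (M). Per the labels' protocols, RNA was extracted with Trizol, first-strand cDNA was made and amplified with the SMART-seq2 method from polyA RNA, and libraries were built with a transposon-based method. Per the submitters' processing notes, the genome build was GRCm38; the aligner, the counting tool, the gene annotation and the way the subgroups were sorted are not given in the sources used here. The deposited values are FPKM, fragment counts scaled for transcript length and mapped fragments, computed by the authors and rounded to 2 decimals per the file headers and the values themselves. The table has 20606 genes with NCBI gene numbers and symbols, 2 symbols stand on 2 lines each and were kept apart, and 0 columns belonged to no listed sample. RefSeq coordinates on GRCm38 were joined by gene number for 20548 genes and used only to give positions.

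Groups were taken from the sample titles. The read depth is unknown, so precision was judged from the spread between the 3 libraries of a group. No label says what the numbers 1 to 3 of the libraries mark. As a check, each library's deviation from its group mean was correlated with those of the other groups over 1830 genes at 50 FPKM or more. The 18 pairs of libraries with the same number had correlations of 0.482 to 0.796, and the 36 pairs with different numbers -0.683 to 0.38. In all, 12 of 12 libraries correlated best with their own number, so each comparison was also fitted with the number as a block.

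Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, keeping 13300 genes with at least 1 FPKM in at least 3 samples. A single linear model of the 4 group means was fitted to all 12 libraries, with a mean-variance trend in the moderated tests. Its 5 contrasts were M-MF against N-MF, M-MyoF against N-MyoF, the difference between these 2 effects, N-MF against N-MyoF and M-MF against M-MyoF. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and a gene passed at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes near 0. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

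Before the data were examined, 49 gene lists of pathways and cell type markers were fixed, with 774 entries for 727 distinct genes, of which 707 matched the table, 1 by an older symbol. The 47 lists with at least 5 tested members were tested with camera, with the correlation between genes preset at 0.01, and adjusted over the lists within a contrast. Camera with an estimated correlation and fry, a self-contained test, were run beside it. A list of mitochondrially encoded genes matched no gene and is not analysed here. Counts of list members use the adjustment over all genes, and the count adjusted over the list alone stands beside them.

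Genes are named by a rule fixed with the lists. It names, per contrast and direction, the 8 genes with the largest change (5 for the difference of effects) among those that passed, did not overlap between groups and had a mean of at least 5 FPKM in the higher group. The overlap condition was dropped for the difference of effects and unnamed gene models were left out. It also names the kynurenine pathway genes, 11 subgroup markers, and up to 4 members with the smallest p of each list described. List members named because they went against their list, such as Cxcl1, Vsir, Tnfrsf14, Fosl1, Klf6, Hk2, Trem1, Rspo1, Por, Pvr, Il1rn, Inhba, Tnfaip2, Gpx3 and P4ha3, were chosen after their values were seen. Kmo, Kynu, Haao, Acmsd and Aadat did not pass the expression filter. Single values of some list members are not reported here.

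The code was tested on simulated data for M-MF against N-MF with 11692 genes, 200 of them changed. Of 50 genes per size, 6% were recovered at a log2 change of 0.1, 88% at 0.25, 96% at 0.5 and 100% at 1, the median absolute error was 0.026, and 5.2% of 153 calls were unchanged genes. In the simulated M-MyoF against N-MyoF, where no gene was changed, 0 genes passed. Alternatives covered pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, 3 scalings (equal sums per library, median-ratio scaling and quantile normalization). The equal sums were larger than the deposited ones, so that setting also tested more genes, 14193, and made the pseudocount smaller against the values. The alternatives also covered a fit on the compared groups only, library weights, other variance priors, the 2 forms of block, each library left out in turn, and other thresholds. Leaving out the 4 libraries numbered 3 was added after seeing the data.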

Results

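Bulk RNA sequencing measured gene expression in 2 subgroups of mouse lung fibroblasts, each taken from normal mice and from mice with lung metastasis. The subgroups are abbreviated MF, the matrix fibroblasts of the series title, and MyoF in the labels, and the 4 groups N-MF, N-MyoF, M-MF and M-MyoF held 3 libraries each. The series concerns breast cancer metastasis to the lung and fibroblasts that express Tdo2, the dioxygenase that opens the tryptophan ring at the start of the kynurenine pathway. Deposited values are FPKM, so the read depth is unknown; they summed to between 528176 and 618478 per library, and between 11466 and 12682 genes reached 1 FPKM. The 10 most abundant genes held 9.18% to 14.7% of the sum, with Gsn at the top in the MF libraries and Scgb1a1 in the MyoF libraries. Libraries of 1 group were nearly alike, with correlations of log2 values between 0.996 and 0.998 and a median coefficient of variation of 1.55% to 1.75% among genes at 100 FPKM or more. No label says that they came from separate mice, so p-values measure only the spread between these libraries, which may be technical, and changes of 2-fold or more are given first. The first principal component held 50.4% of the variance and the next 41.2%, and together they placed each group apart. The 4 libraries numbered 3 scored between -10.1 and -7.24 on the component that held 0.8%, and the other 8 between 2.57 and 6.01.

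**Figure D1:**
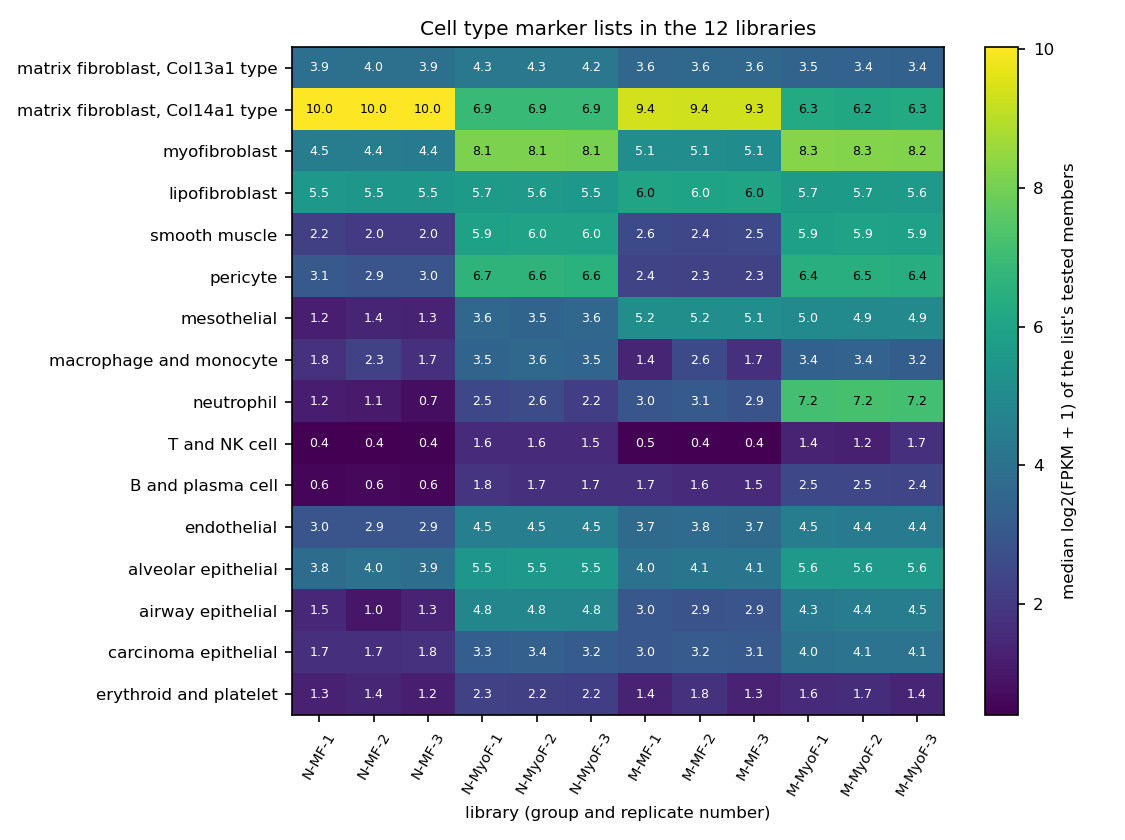
Each cell gives the median log2(FPKM + 1) of a marker list's tested members (vertical axis, 16 lists) in 1 library (horizontal axis, 12 libraries in 4 groups), also shown as colour. The Col14a1-type matrix fibroblast list lay between 9.34 and 10.03 in the MF libraries and between 6.19 and 6.93 in the MyoF libraries, and the neutrophil list reached 7.16 to 7.22 in the M-MyoF libraries.

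The comparison of M-MF with N-MF asked how matrix fibroblasts of lungs with metastasis differ from those of normal lungs. Tdo2 rose 196-fold on the log2(FPKM + 1) scale, from 0.507 ± 0.0764 to 294 ± 3.65 FPKM (mean ± SD, n = 3), with a log2 fold change of 7.62 ± 0.0561 (SE; limma adjusted p = 2.08e-17). Saa3, an acute phase protein, rose 347-fold to 3576 ± 40 FPKM (8.44 ± 0.109). Chil4, a chitinase-like protein, rose from a mean of 0.01 to 290 ± 7.15 FPKM (8.17 ± 0.0329). Among genes that fell, Tgfbi, a matrix adhesion protein induced by TGF-beta, went from 334 ± 7.85 to 39.4 ± 0.391 FPKM (-3.05 ± 0.0299). Angptl7, a secreted angiopoietin-like protein, fell from 283 ± 2.1 to 46.5 ± 0.985 FPKM (-2.58 ± 0.036). In this and the following paragraphs, values after ± are SE for log2 fold changes and SD for FPKM means, with n = 3 libraries per group.

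Of 13300 genes tested, 1578 changed at least 2-fold between M-MF and N-MF at an adjusted p under 0.05, 1240 higher and 338 lower, and 1529 did so without the 4 libraries numbered 3. The 2-fold count was 767 with a pseudocount of 5 and 2397 with 0.1. With no minimum fold 10382 passed, 6153 higher and 4229 lower; the 3 values of 1 group lay all above those of the other for 79.8% of genes, where chance gives 10%. The higher share of calls was 59.3% with values as deposited and 49.7%, 46.6% and 40.4% after rescaling to equal sums, median-ratio scaling and quantile normalization. These put the median of all genes at -0.01, -0.04 and -0.10 instead of 0.08. At 2-fold or more, 1284 were then higher and 584 lower, 1075 and 524, or 942 and 561. Besides Tdo2, Saa3 and Chil4, the largest rises were in Slpi, an inhibitor of leukocyte proteases (152-fold), Spp1, which encodes osteopontin (96-fold), Serpinb2, an inhibitor of plasminogen activators (96-fold), Col6a5, a collagen VI chain (85.2-fold), and Retnla, a resistin-like secreted protein (83.6-fold). Tdo2 lies on chromosome 3 from 81958412 to 81975728 and Saa3 on chromosome 7 from 46711998 to 46719615 in the RefSeq annotation of GRCm38. Besides Tgfbi and Angptl7, the largest falls were in Myoc (-3.02 ± 0.0474), Cytl1 (-2.58 ± 0.0597), Mlana (-2.50 ± 0.133) and C1qtnf3 (-2.42 ± 0.0477), and in Myl7 (-2.56 ± 0.14) and Sln (-2.37 ± 0.0899), genes of atrial muscle. Chil4 and Chil3 are close copies, so their split between the 2 genes is uncertain.

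**Figure D2:**
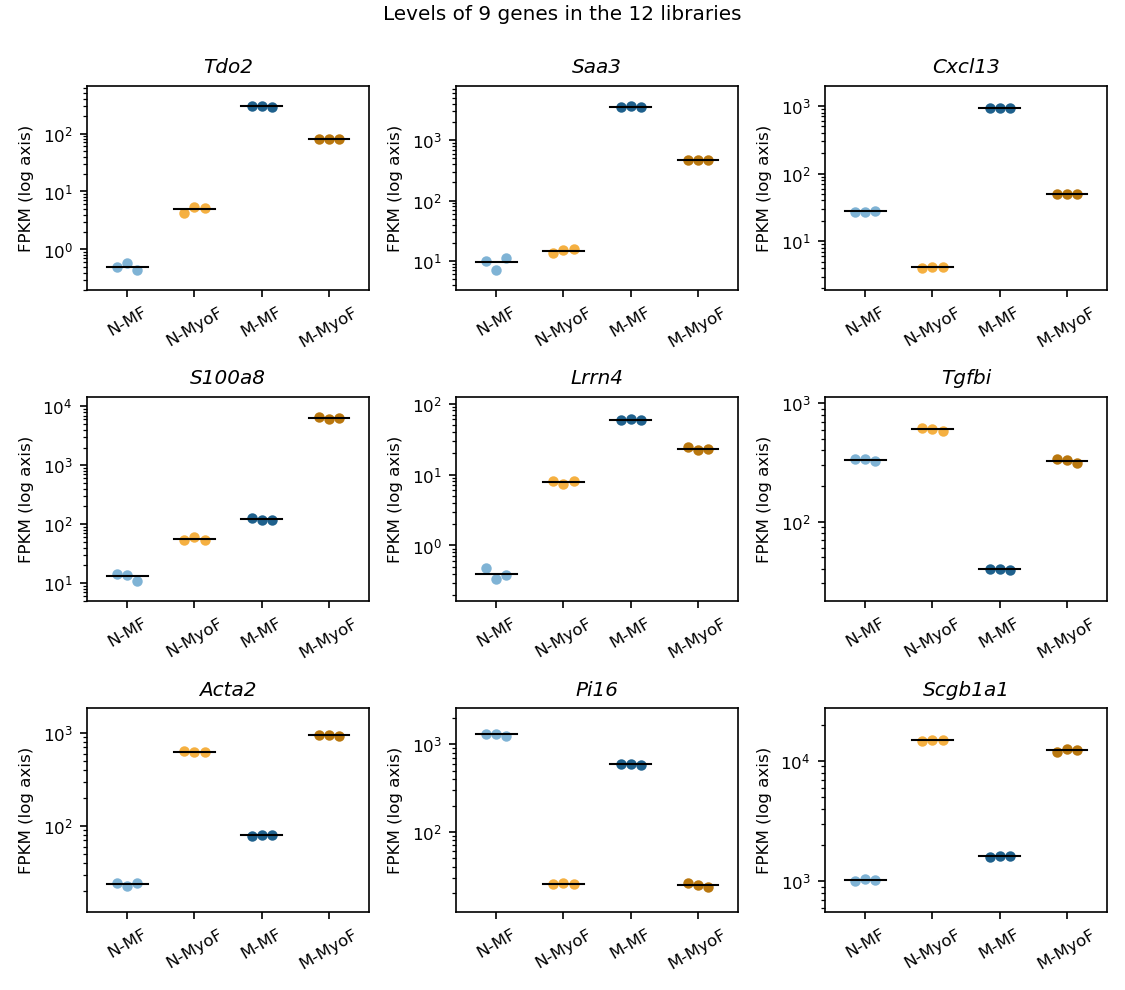
Each panel plots 1 gene's FPKM (vertical log axis) in the 12 libraries (points) of the 4 groups (horizontal axis), with a line at the group mean. Tdo2 had means of 0.507 in N-MF, 4.95 in N-MyoF, 294 in M-MF and 80.3 FPKM in M-MyoF, and S100a8 reached 6325 FPKM in M-MyoF against 121 in M-MF.

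In the kynurenine pathway list, 7 of 8 tested members rose in M-MF and Qprt, which makes the quinolinate-derived NAD precursor, fell (-0.23 ± 0.0734). Tdo2, the gene the series title names, was by far the most abundant of the 3 enzymes that start the pathway: Ido1 rose from 0.03 to 2.00 FPKM (1.54 ± 0.0562) and Ido2 reached 0.597 FPKM (0.64 ± 0.0702). Downstream, the kynurenine aminotransferases Kyat3 (0.82 ± 0.0428), Got2 (0.70 ± 0.0311) and Kyat1 (0.19 ± 0.0669) and the formamidase Afmid (0.52 ± 0.0725) rose. Kyat1 missed the threshold under each of the 3 scalings, without N-MF replicate 3 (0.16) and without M-MF replicate 2 (0.15), and Qprt with a pseudocount of 0.1 (-0.28). As a set the kynurenine pathway passed the camera test (adjusted p = 0.0423), with adjusted p = 0.124 with an estimated correlation. Its adjusted p was 0.0572 with the replicate number as a block, 0.0592 with a pseudocount of 5, 0.0712 without the libraries numbered 3 and 0.0694 to 0.07 without any 1 of the M-MyoF libraries. Kynurenine is a ligand of the aryl hydrocarbon receptor. In the list of that receptor and its targets 4 of 8 rose and 3 fell, and the set did not pass (adjusted p = 0.762). Cyp1b1 stood at 1.51 ± 0.0291, Ahr itself at 0.85 ± 0.0547 and Arnt, its partner, at -0.36 ± 0.0283. Of 18 ferroptosis defence genes 12 rose and 3 fell. Among those that rose were Gpx4, the lipid peroxide reductase (0.86 ± 0.0424), Slc7a11, the cystine importer (0.81 ± 0.0431, from 0.23 to 1.16 FPKM), its partner Slc3a2 (0.99 ± 0.0348) and the ferritin chain Fth1 (0.81 ± 0.0278). Of 13 ferroptosis promotion genes 9 rose, including Acsl4, which activates polyunsaturated fatty acids (2.30 ± 0.0331), and Ncoa4, which delivers ferritin for breakdown (1.77 ± 0.0246), and 3 fell. Neither of the 2 ferroptosis sets passed (adjusted p = 0.159 and 0.146; 0.0419 each without the expression filter). Amino acid carriers rose in 9 of 12 cases, led by Slc7a8 (3.16 ± 0.049), and that set missed the threshold as deposited (adjusted p = 0.0668). It passed after rescaling to equal sums (adjusted p = 0.0232), median-ratio scaling (0.0204), quantile normalization (0.0143), without the expression filter (0.0107) and with a stricter filter of 5 FPKM (0.0459). The count of changed members was the same in each of these 5 lists when adjusted over the list alone.

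Chemokine, cytokine, interferon response and antigen presentation genes rose in M-MF, while 3 other lists of inflammation did not pass. NF-kappaB targets had 8 of 17 genes higher and 8 lower (adjusted p = 0.496), complement 6 of 15 higher and 5 lower (0.744), and prostaglandin synthesis 7 of 10 higher and 2 lower (0.145; 0.0406 without the expression filter). Of 21 chemokines 17 rose, 13 of them at least 2-fold, and Cxcl1 fell (camera adjusted p = 0.000132). Cxcl13, a B cell attractant, rose from 27.6 to 930 FPKM (5.03 ± 0.023), Ccl9 by 3.39 ± 0.0527 and Cxcl9, which attracts activated T cells, by 3.24 ± 0.0457. Of 20 cytokines and acute phase proteins 14 rose and 4 fell (adjusted p = 0.0141, but adjusted p = 0.0787 with an estimated correlation and 0.0644 at the stricter filter). Among the largest were Hp, haptoglobin, at 5.71 ± 0.0401, Lcn2, a siderophore-binding protein, at 5.88 ± 0.0648 and Csf3, the neutrophil growth factor, at 5.02 ± 0.038. In the interferon response 20 of 24 genes rose, such as Gbp4 (2.85 ± 0.0328) and Igtp (2.13 ± 0.0219), and 4 fell (adjusted p = 0.00126). Every tested MHC class I (15 of 15) and class II (7 of 7) presentation gene rose. Examples are H2-K1 (1.93 ± 0.0153), B2m (1.47 ± 0.0109), Cd74, the class II invariant chain (3.42 ± 0.026), and H2-Ab1 (3.37 ± 0.0493). H2 genes are close copies of each other and their single values are uncertain. The 2 presentation sets passed camera (adjusted p = 1.75e-05 and 0.000478), with adjusted p = 0.124 and 0.0787 with an estimated correlation. Genes of the T cell inhibitory ligand list, which also holds enzymes, rose in 10 of 12 cases, while Vsir and Tnfrsf14 fell. Among those that rose were Lgals1 (2.31 ± 0.0198) and the enzymes Nt5e, which makes adenosine (2.76 ± 0.0438), and Nos2 (2.45 ± 0.0695). The list of T cell inhibitory ligands passed narrowly (adjusted p = 0.0423), with adjusted p = 0.13 with an estimated correlation. It had 0.057 with the replicate number as a block, 0.051 without N-MyoF replicate 2, 0.0551 with only the 2 compared groups in the fit and 0.0783 at the stricter filter. When adjusted over the list alone, 19 instead of 18 cytokine genes changed and the other counts in this paragraph were the same. In the same libraries neutrophil markers had a median log2 fold change of 2.07 and mesothelial markers 3.82.

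Cell cycle, glycolysis and ribosomal genes were higher in M-MF. All 24 proliferation genes rose, 22 at least 2-fold, with a list median of 3.11, Top2a, the mitotic topoisomerase, at 3.59 ± 0.0431 and Cdk1 at 3.57 ± 0.046 (adjusted p = 2.8e-09). Of 16 glycolysis genes 15 rose, such as Eno1 (2.70 ± 0.0246) and the glucose carrier Slc2a1 (2.70 ± 0.0315), and Hk2 fell (adjusted p = 2.63e-05; adjusted p = 0.124 with an estimated correlation). The hypoxia response rose in 12 of 14 genes, including Egln3 (3.83 ± 0.0458) and Bnip3 (1.82 ± 0.0224), with adjusted p = 0.00045. Ribosomal protein genes rose in 31 of 32 cases with a median of 0.67 (adjusted p = 6.19e-07). The 21 tested oxidative phosphorylation genes rose with a median of 0.49 (adjusted p = 0.000132; adjusted p = 0.0746 with an estimated correlation). Of 17 cholesterol synthesis genes 14 rose, led by Sqle (1.90 ± 0.0443), with adjusted p = 0.0321, adjusted p = 0.13 with an estimated correlation and 0.0734 at the stricter filter. Of 21 immediate early genes, which also respond to tissue dissociation, 19 fell, and Fosl1 and Klf6 rose (adjusted p = 1.76e-06; adjusted p = 0.124 with an estimated correlation). Egr2 fell by -1.64 ± 0.0222, Egr1 by -1.06 ± 0.0166 and Fos by -0.79 ± 0.0129. Adjusted over the list alone, 14 instead of 13 hypoxia genes changed and the other counts in this paragraph were the same. In the same libraries carcinoma epithelial markers had a median log2 fold change of 0.87, neutrophil markers 2.07 and mesothelial markers 3.82. Which cells gave the rises in this paragraph was not tested.

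Most genes of the 2 matrix fibroblast lists fell in M-MF, while other mesenchymal lists and single matrix genes moved both ways. Myofibroblast markers rose in 9 of 16 cases and fell in 7 (adjusted p = 0.835), smooth muscle genes rose in 7 of 11 and fell in 2 (0.463), and pericyte genes rose in 5 of 12 and fell in 5 (0.48), none of them past the threshold as a set. In the Col13a1-type matrix fibroblast list 12 of 15 fell, including Inmt (-2.22 ± 0.0165) and the lung mesenchyme regulator Tcf21 (201 to 72.3 FPKM, -1.46 ± 0.0389). In the Col14a1-type list 11 of 17 fell and 5 rose, including Fbln1 (-1.71 ± 0.0154) and Dpt (-1.16 ± 0.013). The 2 matrix fibroblast sets passed with adjusted p = 0.00045 and 0.00416, and had adjusted p = 0.0537 and 0.081 with an estimated correlation. Of the fixed subgroup markers, Pdgfra (-0.25 ± 0.0265), Col14a1 (-0.77 ± 0.0187), Itga8 (-0.82 ± 0.0449), Npnt (-0.13 ± 0.0275), Hhip (-0.64 ± 0.0248) and Aspn (-1.32 ± 0.0176) fell. Acta2, smooth muscle actin (24 to 79.7 FPKM, 1.69 ± 0.0261), Tagln (1.31 ± 0.0307) and Lgr6 (0.39 ± 0.035) rose, and Col13a1 had 0.02 ± 0.0754. Fibronectin, Fn1 (2.27 ± 0.022), the crosslinking enzymes Tgm2 (1.31 ± 0.0236) and Lox (1.28 ± 0.0277) and the metalloprotease inhibitor Timp1 (2.76 ± 0.0211) rose. Lum (-0.96 ± 0.0163), Ccn2 (-1.17 ± 0.0192), Timp3 (-1.85 ± 0.0163) and Col1a2 (-0.51 ± 0.0164) fell. The lists of these matrix genes did not pass camera. Adjusted p was 0.511 for matricellular, 0.101 for crosslinking (0.0184 without the expression filter), 0.768 for protease and 0.134 for fibrillar collagen genes. Genes of cancer-associated fibroblast activation rose in 9 of 16 cases and fell in 6, without passing as a set (adjusted p = 0.461). In the basement membrane list 10 of 15 fell, such as Col4a3 (-2.18 ± 0.0418) and Lama2 (-1.33 ± 0.0255), and 4 rose (adjusted p = 0.00815; adjusted p = 0.263 with an estimated correlation). The counts of changed members given in this paragraph were the same adjusted over the list alone. The median of mesothelial markers was 3.82 in the same libraries.

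Markers of other cell types moved with these changes. Mesothelial genes rose in 9 of 10 cases, all at least 2-fold, with a median of 3.82 (adjusted p = 0.000132). Lrrn4 went from 0.4 to 59 FPKM (5.42 ± 0.0455), Upk1b by 4.49 ± 0.0458 and Gpm6a by 3.82 ± 0.0332, and Rspo1 had -0.13. Neutrophil markers rose in 10 of 13 cases with a median of 2.07, and Trem1 fell (adjusted p = 0.0123; adjusted p = 0.219 with an estimated correlation). Ngp went from 0.49 to 27.2 FPKM (4.25 ± 0.0744) and S100a8 from 13 to 121 FPKM (3.13 ± 0.0773). Of 12 carcinoma epithelial markers 9 rose, with the keratins Krt8 at 4.73 ± 0.074 and Krt18 at 4.41 ± 0.0311, and 2 fell (adjusted p = 0.0207; adjusted p = 0.124 with an estimated correlation). The keratin Krt19 is a member of both the carcinoma epithelial and the mesothelial list. Which cells gave the keratins was not tested. Airway epithelial markers rose in 9 of 10 cases with a median of 0.71, and the set missed the threshold as deposited (adjusted p = 0.0835). It passed after the 3 rescalings (0.0316, 0.0288 and 0.0331) and without the expression filter (0.0184). Macrophage and monocyte markers rose in 4 of 16 cases and fell in 4, with Chil3 at 5.69 ± 0.0513, and the set did not pass (adjusted p = 0.762; its median of -0.11 and mean of 0.46 differ in sign). Jchain, an antibody joining chain and 1 of 4 tested B and plasma cell markers, rose by 4.35 ± 0.0751. Over all 47 lists tested between M-MF and N-MF, 21 passed camera. The calls that held with an estimated correlation were those of proliferation, ribosomal protein, chemokine, interferon response, hypoxia response and mesothelial genes (adjusted p = 0.0151, 0.0151, 0.0239, 0.0331, 0.0295 and 0.0253). Counts of changed members here were the same adjusted over the list alone.

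**Figure D3:**
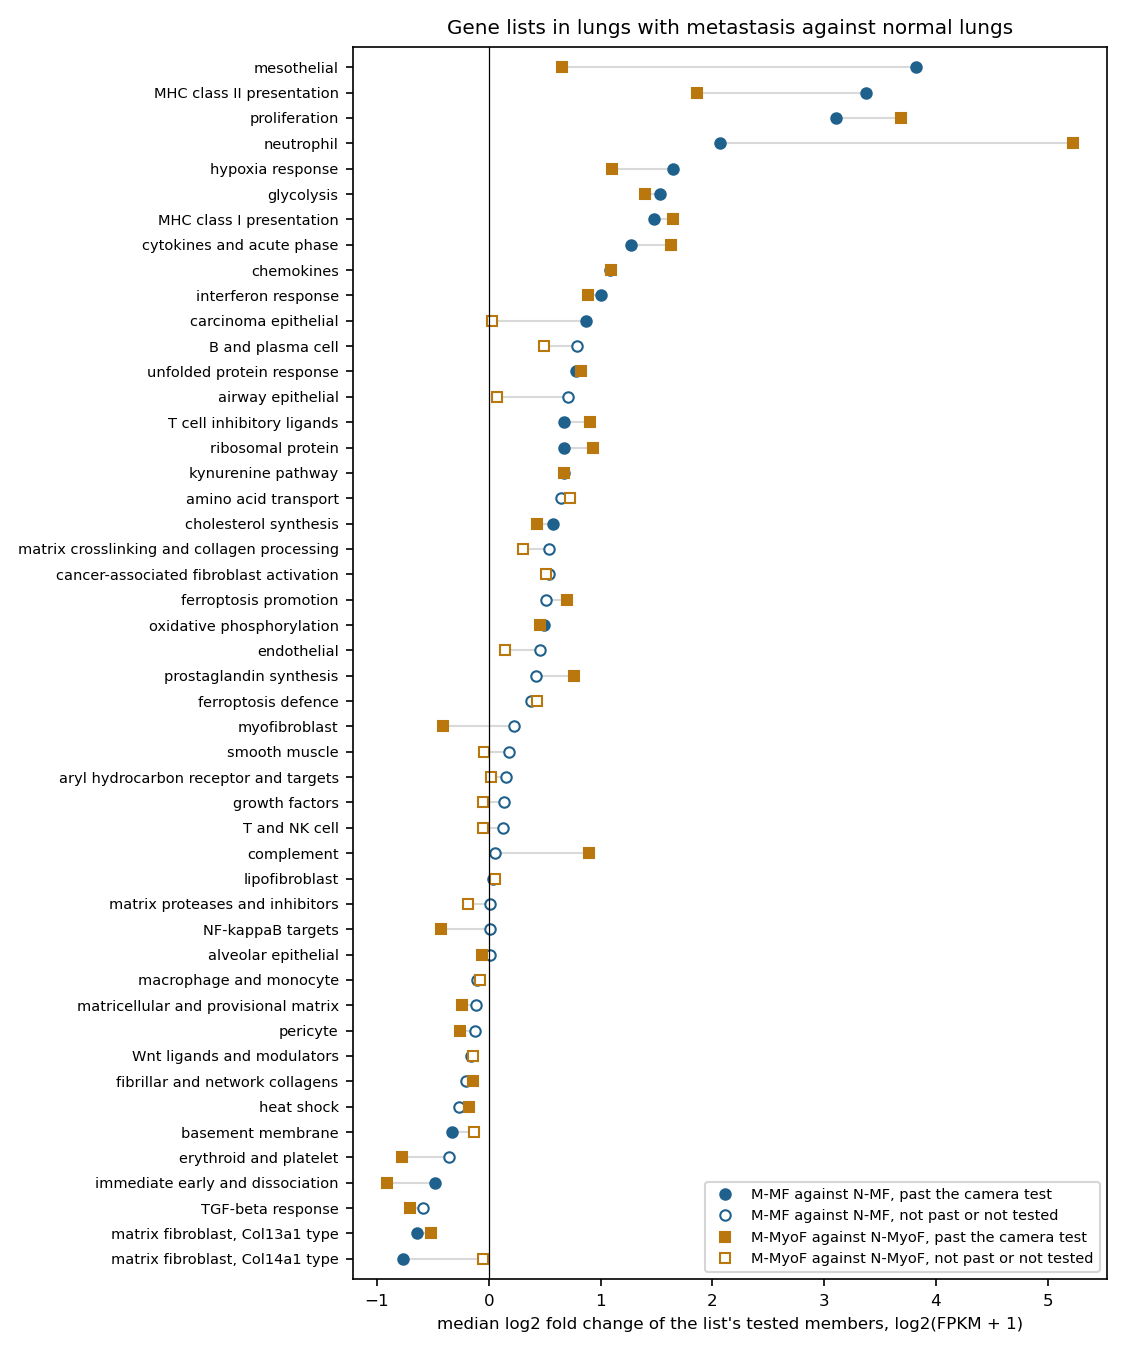
For each gene list (vertical axis), points give the median log2 fold change of its tested members (horizontal axis) in M-MF against N-MF (circles) and M-MyoF against N-MyoF (squares), filled where the camera adjusted p was under 0.05. Proliferation genes had medians of 3.11 and 3.69, mesothelial genes 3.82 and 0.65 and neutrophil genes 2.07 and 5.22.

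The comparison of M-MyoF with N-MyoF put the same question to the other subgroup. The 4 largest rises were in Ngp, Ifitm6, Retnla and S100a8. S100a8, a subunit of calprotectin, went from 55.6 ± 3.51 to 6325 ± 223 FPKM (112-fold, 6.81 ± 0.0773). Ngp, a neutrophil granule protein, rose from 6.61 ± 0.343 to 1305 ± 23.8 FPKM (7.42 ± 0.0744) and Retnlg from 4.39 ± 1.11 to 551 ± 9.35 FPKM (6.70 ± 0.141). Retnla rose 156-fold to 2285 ± 59.5 FPKM and Lcn2 81.7-fold to 1134 ± 39.3 FPKM. Among genes that fell were cartilage matrix genes, Chad (211 ± 3.39 to 15 ± 0.161 FPKM, -3.73 ± 0.0345), Cnmd (-3.41 ± 0.0502), Ucma (-3.31 ± 0.0879) and Otor (-3.37 ± 0.0682). So were the atrial muscle genes Nppa (-3.48 ± 0.0748) and Myl7 (-3.23 ± 0.14). In normal lung Chad stood at 6.04 FPKM in N-MF against 211 in N-MyoF, and Myl7 at 10.9 against 289. Whether RNA of other cells gave these cartilage and atrial muscle genes, here or in M-MF against N-MF, was not tested. Cytl1 fell by 4.21 ± 0.0597, and Glycam1, at 46.5 ± 2.8 FPKM in N-MyoF, was listed at 0 in all 3 M-MyoF libraries.

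Between M-MyoF and N-MyoF, 1941 genes changed at least 2-fold, 1510 higher and 431 lower, and 1805 did so without the 4 libraries numbered 3. With a pseudocount of 5 the 2-fold count was 1072, 881 higher and 191 lower, and with 0.1 it was 2585. With no minimum fold 10734 of 13300 passed, 6529 higher and 4205 lower, and the groups did not overlap for 82.2% of genes, where chance gives 10%. The higher share was 60.8% as deposited and 45.3%, 45.7% and 41.1% after the 3 rescalings named above, which put the median of all genes at -0.06, -0.05 and -0.11 instead of 0.11. At 2-fold or more, 1356 genes were then higher and 808 lower, 1176 and 628, or 1123 and 778. Ifitm6 (7.34 ± 0.136), Cstdc5 (6.64 ± 0.153) and Stfa2 (6.38 ± 0.117) completed the largest rises; Cstdc5 and Stfa2 belong to a cluster of close stefin copies, so their single values are uncertain.

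Tdo2 rose in M-MyoF as well, from 4.95 ± 0.547 to 80.3 ± 0.582 FPKM (3.78 ± 0.0561), with Ido1 at 2.06 ± 0.0562, Got2 at 0.86 ± 0.0311 and Kyat3 at 0.53 ± 0.0428. All 8 tested genes of the kynurenine pathway rose (adjusted p = 0.0242; adjusted p = 0.0961 with an estimated correlation). Afmid (0.24 ± 0.0725) and Kyat1 (0.27 ± 0.0669) missed the threshold under each of the 3 rescalings, and Qprt (0.31 ± 0.0734) under quantile normalization. Of 18 ferroptosis defence genes 13 rose, including Scd1 (1.80 ± 0.0359) and Slc7a11 (1.13 ± 0.0431), and 3 fell, without passing as a set (adjusted p = 0.137; 0.0334 without the expression filter). Ferroptosis promotion genes rose in 11 of 13 cases, including Acsl4 (1.78 ± 0.0331), and Por and Sat1 fell (adjusted p = 0.0242; adjusted p = 0.153 with an estimated correlation and 0.0721 at the stricter filter). All 24 proliferation genes rose (median 3.69, Top2a 3.97 ± 0.0431, adjusted p = 7.85e-09), as did all 32 ribosomal protein genes (median 0.93, adjusted p = 9.38e-08). Glycolysis genes rose in 15 of 16 cases, with Eno1 at 3.50 ± 0.0246 (adjusted p = 2.58e-05; adjusted p = 0.101 with an estimated correlation). Of 21 immediate early genes 19 fell and Fosl1 rose (adjusted p = 2.25e-08; adjusted p = 0.0961 with an estimated correlation), among them Egr2 (-1.65 ± 0.0222) and Btg2 (-0.98 ± 0.0128). Neutrophil markers rose with a median of 5.22 in these libraries. The same numbers of members changed when adjusted over the list alone.

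Chemokines rose in 18 of 21 cases and Cxcl1 fell (adjusted p = 0.00125), with Ccl8 at 4.40 ± 0.0921, Cxcl13 at 3.31 ± 0.023 and the eotaxin Ccl11 at 2.59 ± 0.0284. Cytokines and acute phase genes rose in 17 of 20 cases (adjusted p = 0.00148), Csf3 by 5.38 ± 0.038, and Il6 (-1.73 ± 0.0335) and Il1rn fell. The interferon response rose in 20 of 24 genes (adjusted p = 0.00203). All 15 MHC class I and 7 class II presentation genes rose, with Psmb8 at 3.29 ± 0.0496 and Cd74 at 1.95 ± 0.026 (adjusted p = 1.5e-05 and 0.0026; adjusted p = 0.101 and 0.0961 with an estimated correlation). Genes of the T cell inhibitory ligand list rose in 10 of 12 cases and Pvr fell. Cd274, which encodes PD-L1, went from 3.45 to 12 FPKM (1.55 ± 0.0434), and the set had adjusted p = 0.0242 and adjusted p = 0.0984 with an estimated correlation. Complement genes rose in 10 of 15 cases, C3 by 2.94 ± 0.0235 and Cfb by 2.21 ± 0.0214, and 3 fell (adjusted p = 0.0338; adjusted p = 0.234 with an estimated correlation and 0.0599 at the stricter filter). The list of NF-kappaB targets fell in 13 of 17 genes, with Icam1 at -2.06 ± 0.0158 and Birc3 at -1.46 ± 0.0231, and rose in 4 (adjusted p = 0.00196; adjusted p = 0.0961 with an estimated correlation). Neutrophil markers had a median of 5.22 in the same libraries. For these lists, counts adjusted over the list alone were the same.

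TGF-beta response genes fell in 12 of 15 cases in M-MyoF and Inhba rose (adjusted p = 0.00018), with Tgfb3 at -1.31 ± 0.0268 and the Smad repressor Skil at -1.14 ± 0.0264. Col13a1-type matrix fibroblast genes fell in 12 of 15 cases, with Inmt at -1.49 ± 0.0165 (adjusted p = 0.000209). Myofibroblast markers fell in 10 of 16 cases, Hhip from 2231 to 787 FPKM (-1.50 ± 0.0248) and Aspn by -0.83 ± 0.0176 among them. They rose in 5, such as Acta2 (0.59 ± 0.0261) and Tagln (0.59 ± 0.0307). The myofibroblast set had adjusted p = 0.0242, adjusted p = 0.153 with an estimated correlation, and 0.0524, 0.0528 and 0.0574 after the 3 rescalings. Of the other fixed markers Lgr6 (-0.88 ± 0.035), Col14a1 (-0.77 ± 0.0187), Col13a1 (-0.73 ± 0.0754), Npnt (-0.77 ± 0.0275), Tcf21 (-0.52 ± 0.0389) and Itga8 (-0.49 ± 0.0449) fell. Pdgfra had 0.06 ± 0.0265 as deposited and missed the threshold there (limma adjusted p = 0.0524). It passed as a fall after the 3 rescalings (-0.12, -0.12 and -0.14). It passed as a rise with the replicate number as a block (0.06), without N-MyoF replicate 1 (0.08) and without M-MyoF replicate 3 (0.07). No direction is therefore given for Pdgfra. Lum fell from 1003 to 165 FPKM (-2.60 ± 0.0163), Thbs1 had -1.63 ± 0.0199, Col11a1 -2.04 ± 0.0523 and Col3a1 -0.56 ± 0.0139, while Fn1 (1.94 ± 0.022) and Timp1 (3.38 ± 0.0211) rose. Genes of cancer-associated fibroblast activation rose in 10 of 16 cases and fell in 4, without passing camera as a set (adjusted p = 0.3). Adjusted over the list alone, 14 instead of 13 Col13a1-type genes changed and the other counts were the same.

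All 13 neutrophil markers rose at least 2-fold in M-MyoF, with a median of 5.22 (adjusted p = 2.06e-06; adjusted p = 0.0649 with an estimated correlation), including Mmp8 (5.54 ± 0.0546), Mmp9 (4.68 ± 0.043) and Il1r2 (4.46 ± 0.0282). Macrophage and monocyte markers rose in 5 of 16 cases and fell in 7, with Itgam at 3.43 ± 0.0389 and Ear2 at -2.48 ± 0.0486, and did not pass (adjusted p = 0.336). Mesothelial markers rose in 8 of 10 cases, Msln by 1.76 ± 0.0369 (median 0.65, adjusted p = 0.0279; adjusted p = 0.0966 with an estimated correlation and 0.0728 at the stricter filter). Krt8 (4.02 ± 0.074) and Krt18 (3.53 ± 0.0311) rose, although the carcinoma epithelial list did not pass (5 of 12 rose, 4 fell, adjusted p = 0.626). Over the 47 lists 30 passed camera between M-MyoF and N-MyoF. The calls that held with an estimated correlation were those of proliferation and ribosomal protein genes (adjusted p = 0.0113 each) and of the Col13a1-type, TGF-beta response, chemokine, cytokine and interferon lists (adjusted p = 0.0396 each). Each of these counts was the same adjusted over the list alone.

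Fold changes of the 2 subgroups were correlated across the 13300 genes (Pearson 0.723, Spearman 0.71), a description only, since genes are not independent replicates; the 2 comparisons share no library. At 2-fold or more, 831 genes rose in both subgroups where independent lists would share 141, 126 fell in both where they would share 11, and 8 went in opposite directions. Independence is a reference only, since libraries of the same number deviated together across groups. Neutrophil markers (medians 2.07 in MF and 5.22 in MyoF) and mesothelial markers (3.82 and 0.65) also rose in both. The overlap therefore does not show by itself a response shared by the fibroblasts.

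**Figure D4:**
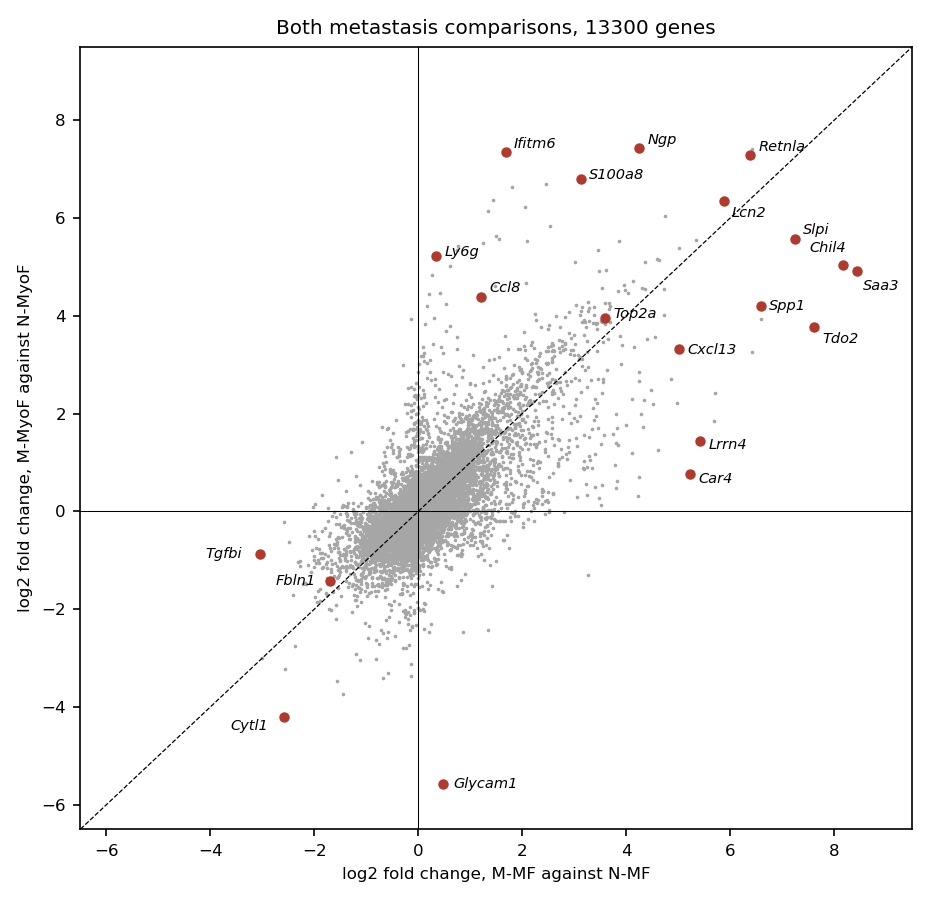
Each grey point is 1 of 13300 genes, with its log2 fold change in M-MF against N-MF on the horizontal axis and in M-MyoF against N-MyoF on the vertical axis; named genes are red and the dashed line marks equal changes. Tdo2 stood at 7.62 and 3.78, Lrrn4 at 5.42 and 1.44, and S100a8 at 3.13 and 6.81.

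The difference between the 2 effects tested which changes were larger in 1 subgroup. Tdo2 rose more in MF, by 3.84 ± 0.0794 on the log2 scale (adjusted p = 1.02e-12), as did Saa3 (3.52 ± 0.154). So did Car4, a membrane carbonic anhydrase (17.8 to 702 FPKM in MF and 65.5 to 111 in MyoF, 4.47 ± 0.037), and the mesothelial markers Lrrn4 (3.98 ± 0.0644) and Upk3b (3.92 ± 0.0971). Neutrophil-associated genes rose more in MyoF: Ifitm6 (-5.66 ± 0.192), Stfa2 (-4.93 ± 0.166), Ly6g (-4.89 ± 0.111), Cstdc5 (-4.84 ± 0.216) and Cd177 (-4.81 ± 0.0534). Bpifa1, an airway secretory gene, rose from 0.54 to 13.9 FPKM in MF and fell from 101 to 40.8 FPKM in MyoF (4.57 ± 0.0817). Tgfbi fell more in MF (-2.17 ± 0.0423).

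The 2 effects differed by at least 2-fold for 944 genes, 509 with the more positive change in MF and 435 in MyoF, and for 815 without the 4 libraries numbered 3. With no minimum fold 8566 differed, 3510 and 5056. The 2-fold count was 1241 (762 and 479) after rescaling to equal sums, which also raised the genes tested to 14193 and made the pseudocount smaller against the values, 456 (238 and 218) with a pseudocount of 5 and 1448 with 0.1. The share more positive in MF was 41% as deposited, 52.7% after rescaling to equal sums, 47.1% after median-ratio scaling and 47.2% after quantile normalization. Mesothelial genes were more positive in MF in 9 of 10 cases (median 2.06, adjusted p = 2.07e-07). The mesothelial list's median log2(FPKM + 1) was 5.13 to 5.17 in the M-MF libraries and 4.93 to 4.98 in M-MyoF. In N-MF it was 1.19 to 1.41 and in N-MyoF 3.5 to 3.58, so the subgroups differed more in normal lung than in metastasis. Neutrophil genes were more positive in MyoF in 13 of 13 cases (median -3.30, adjusted p = 7e-09, and adjusted p = 0.0539 with an estimated correlation). MHC class II genes rose more in MF in 6 of 7 cases, Cd74 by 1.47 ± 0.0368 (adjusted p = 0.00151; adjusted p = 0.105 with an estimated correlation). Complement genes had the more positive change in MyoF in 11 of 15 cases, with C3 at -1.71 ± 0.0332 (adjusted p = 0.00111; adjusted p = 0.143 with an estimated correlation). NF-kappaB targets were more positive in MF in 12 of 17 cases, including Tnfaip3 (1.37 ± 0.0273). They were more negative in 3, Ptgs2 (-1.60 ± 0.0311), Vcam1 (-1.60 ± 0.0441) and Tnfaip2 (adjusted p = 0.00111; adjusted p = 0.0934 with an estimated correlation). Myofibroblast markers were more positive in MF in 10 of 16 cases, with Acta2 at 1.10 ± 0.037 (adjusted p = 0.0173; adjusted p = 0.226 with an estimated correlation). Col14a1-type genes were more negative in MF in 10 of 17 cases, with Scara5 at -2.49 ± 0.0381 and Igfbp4 at -1.84 ± 0.0231. Their call (adjusted p = 0.0409) was lost in other settings (adjusted p = 0.214 with an estimated correlation, 0.0757 with condition and replicate number together as a block, 0.074 at the stricter filter and 0.171 after quantile normalization). Proliferation genes rose more in MyoF in 20 of 24 cases, Rrm2 by -1.35 ± 0.0499, with adjusted p = 0.00104, adjusted p = 0.0539 with an estimated correlation and 0.515 with a pseudocount of 0.1. The kynurenine pathway as a set did not differ past the threshold (adjusted p = 0.779): besides Tdo2, Kyat3 and Afmid were more positive in MF and Ido1, Qprt and Got2 in MyoF. Afmid lost its call without any 1 of 7 libraries (0.22 to 0.27; replicate 1 of each group, replicate 2 of N-MF and M-MyoF, and replicate 3 of N-MyoF), Ido1 with a pseudocount of 0.1 and Got2 after rescaling to equal sums. Of 47 lists 17 passed camera, and that of mesothelial genes held with an estimated correlation (adjusted p = 0.015). Adjusted over the list alone, 16 instead of 15 Col14a1-type genes differed and the other counts in this paragraph were the same.

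N-MF and N-MyoF were compared to describe the subgroups in normal lung. Genes of adventitial fibroblasts were far higher in N-MF. Pi16 stood at 1295 ± 35.9 against 25.6 ± 0.686 FPKM (48.7-fold, 5.61 ± 0.0321) and Scara5, a ferritin receptor, at 714 ± 9.36 against 9.37 ± 0.307 FPKM (6.11 ± 0.0269). Serpinf1 stood at 2309 ± 48.4 against 53.9 ± 2.68 FPKM (5.40 ± 0.0373) and Ccl11 at 319 ± 5.57 against 7.27 ± 0.322 FPKM (5.27 ± 0.0284). Contractile and myofibroblast genes were lower in N-MF. Acta2 stood at 24 against 628 FPKM (-4.65 ± 0.0261), Tagln at 10.8 against 292 FPKM (-4.64 ± 0.0307), Hhip at 67.8 against 2231 FPKM (-5.02 ± 0.0248) and Lgr6 at 1.52 against 83.3 FPKM (-5.06 ± 0.035). Haemoglobin genes were the most reduced, Hbb-b1 at 28 ± 3.66 in N-MF against 3826 ± 50.4 FPKM in N-MyoF (-7.05 ± 0.11). Hba-a1 and Hba-a2 are near-identical copies with an SD of 1090 FPKM each in N-MyoF, and their values are uncertain (-6.67 ± 0.346 and -7.03 ± 0.271).

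At least 2-fold differences numbered 2232 between N-MF and N-MyoF, 649 higher and 1583 lower in N-MF, and 2118 without the libraries numbered 3 (1107 with a pseudocount of 5). With no minimum fold 10912 genes passed, 3254 higher and 7658 lower, and the groups did not overlap for 82.4%, where chance gives 10%. The higher share was 29.8% as deposited, 31% after rescaling to equal sums (756 higher and 1933 lower at 2-fold), 50.3% after median-ratio scaling and 52.1% after quantile normalization. The last 2 put the median of all genes at -0.004 and 0.03 instead of -0.21. Of the 2-fold differences 858 were then higher and 1225 lower, or 872 and 1066. Also higher in N-MF were Sfrp4 (5.11 ± 0.0513), Entpd2 (5.08 ± 0.0394), Ifi205 (5.01 ± 0.0713) and Itgbl1 (4.93 ± 0.0506). Also lower were Hbb-b2, Bpifa1 (-6.06 ± 0.0578), Agt, angiotensinogen (-5.15 ± 0.0387), Pnmt (-5.15 ± 0.117) and Glycam1, listed at 0 in N-MF. Tdo2 was lower in N-MF (0.507 against 4.95 FPKM, -1.98 ± 0.0561) and Qprt higher (2.35 ± 0.0734). The kynurenine pathway did not pass as a set (1 higher, 7 lower, adjusted p = 0.526). Afmid (-0.30 ± 0.0725), Kyat1 (-0.24 ± 0.0669) and Got2 (-0.17 ± 0.0311) lost the call or turned under median-ratio scaling or quantile normalization.

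Col14a1-type genes were higher in N-MF in 16 of 17 cases, with Gpx3 lower (adjusted p = 2.66e-14). Myofibroblast (16 of 16, adjusted p = 5.24e-07), smooth muscle (11 of 11, 6.33e-05) and pericyte genes (10 of 12, 0.00595; adjusted p = 0.0919 with an estimated correlation) were lower. The Col13a1-type list divided, with 8 genes higher and 7 lower. Pdgfra (3.12 ± 0.0265), Tcf21 (2.20 ± 0.0389) and Inmt (3.07 ± 0.0165) were higher and Npnt (-1.62 ± 0.0275), Itga8 (-1.17 ± 0.0449) and Col13a1 (-0.58 ± 0.0754) lower. As a set the matrix fibroblast, Col13a1 type list had adjusted p = 0.0453, and adjusted p = 0.165 with an estimated correlation. Other settings gave 0.0571 with condition and replicate number together as a block, 0.051 without the libraries numbered 3, 0.0511 without N-MyoF replicate 2, 0.0507 without M-MF replicate 2, 0.0508 with only the 2 compared groups, and 0.168 and 0.245 after median-ratio scaling and quantile normalization. Fibrillar collagens were higher in N-MF in 13 of 17 cases, with Col1a1 at 2945 against 408 FPKM (2.85 ± 0.0234) and Col1a2 at 3.20 ± 0.0164. Complement genes were higher in 9 of 15, with C3 at 4.26 ± 0.0235. The 2 sets passed (adjusted p = 1.11e-05 and 0.000464; adjusted p = 0.0952 each with an estimated correlation). Markers of other cell types were lower in N-MF libraries. They were 14 of 15 alveolar (Sftpc 1228 against 4051 FPKM, -1.72 ± 0.0175), 10 of 10 airway epithelial (Scgb1a1 1020 against 14807 FPKM, -3.86 ± 0.0186), 13 of 14 endothelial (Cldn5 -1.71 ± 0.0195), 16 of 16 macrophage and monocyte (Lyz2 -1.92 ± 0.0233) and 8 of 10 mesothelial genes (Msln -3.10 ± 0.0369). These 5 sets had adjusted p = 0.00149, 0.00287, 0.00201, 0.00287 and 0.03, and adjusted p = 0.0496, 0.0516, 0.0952, 0.273 and 0.0952 with an estimated correlation; the mesothelial call had 0.0508 with only the 2 compared groups in the fit. Of 47 lists 23 passed; those that held with an estimated correlation were the Col14a1-type (adjusted p = 0.00391), myofibroblast, smooth muscle and unfolded protein response (0.0354 each) and alveolar lists. Counts of changed members here were the same adjusted over the list alone.

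The last comparison, M-MF against M-MyoF, described the subgroups in lungs with metastasis. Tdo2 was higher in M-MF, at 294 ± 3.65 against 80.3 ± 0.582 FPKM (1.86 ± 0.0561), the opposite of its order in normal lung. Mrgprg, a receptor gene of the Mas-related family, stood at 544 ± 6.54 against 6.19 ± 0.3 FPKM (75.8-fold, 6.24 ± 0.0315). Apod, apolipoprotein D, stood at 327 ± 5.17 against 5.44 ± 0.144 FPKM (5.67 ± 0.0247) and Cxcl13 at 930 ± 9.06 against 49.6 ± 0.517 FPKM (4.20 ± 0.023). S100a8, S100a9 and Retnlg were lower in M-MF, S100a9 at 77.7 ± 4.1 against 4638 ± 79.1 FPKM (-5.88 ± 0.0631), as were the haemoglobins, with Hbb-b1 at -7.92 ± 0.11.

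At least 2-fold differences numbered 1804, 631 higher and 1173 lower in M-MF, and 1677 without the libraries numbered 3 (861 with a pseudocount of 5 and 2768 with 0.1). With no minimum fold 11320 genes passed, 2536 higher and 8784 lower, and the groups did not overlap for 85.6%, where chance gives 10%. The higher share was 22.4% as deposited, 28.8% after rescaling to equal sums (780 higher and 1247 lower at 2-fold), 46.1% after median-ratio scaling and 47.3% after quantile normalization. The last 2 put the median of all genes at -0.035 and -0.02 instead of -0.29. Of the 2-fold differences 853 were then higher and 757 lower, or 890 and 698. Also higher in M-MF were Sfrp4, Ifi205, Pi16 (4.53 ± 0.0321), Dpep1 (4.43 ± 0.035) and Htra3 (4.25 ± 0.0199). The order of the subgroup markers was that of normal lung for Pdgfra (2.81 ± 0.0265), Tcf21 (1.25 ± 0.0389) and Col14a1 (0.92 ± 0.0187). It was so for Acta2 (-3.56 ± 0.0261), Tagln (-3.92 ± 0.0307), Hhip (-4.16 ± 0.0248), Aspn (-2.28 ± 0.0176), Lgr6 (-3.80 ± 0.035), Npnt (-0.97 ± 0.0275) and Itga8 (-1.50 ± 0.0449), and Col13a1 had 0.16 ± 0.0754. Col13a1 passed after the 3 rescalings (0.27, 0.38 and 0.53), without M-MF replicate 1 or 3 (0.20 each) and without N-MF replicate 2 (0.16). Col14a1-type genes were higher in M-MF in 16 of 17 cases, and Gpx3 was lower (adjusted p = 1.74e-17). Myofibroblast genes were lower in 16 of 16 (1.26e-06) and smooth muscle genes in 11 of 11 (0.000171). Chemokines were higher in 12 of 21 cases and lower in 7 (adjusted p = 2.43e-05), and matrix crosslinking genes higher in 14 of 15, with Loxl1 at 1.89 ± 0.0194 and P4ha3 lower (adjusted p = 4.47e-10). Proliferation genes were lower in M-MF in 24 of 24 cases, with Mki67 at -1.04 ± 0.0413 (adjusted p = 0.000657). Neutrophil genes were lower in 13 of 13 with a median of -4.97 (adjusted p = 2.43e-05; adjusted p = 0.0569 with an estimated correlation). Alveolar markers were lower in 14 of 15 cases (adjusted p = 0.00503) and Scgb1a1 stood at 1606 against 12279 FPKM (-2.93 ± 0.0186). Ribosomal protein genes, 3 higher and 22 lower as deposited, were 20 higher and 2 lower after median-ratio scaling, so no direction is given for them. Of 47 lists 24 passed, and 11 held with an estimated correlation: the Col14a1-type (adjusted p = 0.00191), chemokine and unfolded protein response (0.0191 each), myofibroblast, smooth muscle, crosslinking, matrix protease and prostaglandin synthesis (0.0408 each), and mesothelial, alveolar and proliferation lists (0.0447 each). The mesothelial call had adjusted p = 0.00427 as deposited, 0.0607 after median-ratio scaling and 0.0895 after quantile normalization. The same numbers of members changed when adjusted over the list alone.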

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

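A test of the difference between the 2 metastasis effects picked out the results here. Of 53 genes named for the 2 metastasis comparisons or their difference, 49 had different effects in MF and MyoF, against 8566 of all 13300; 10 of the 53 were named for the size of this very difference. The 25 that differed by at least 4-fold are given with the log2 difference, positive where the change was more positive in MF. More positive in MF were Glycam1 (6.04), Bpifa1 (4.57), Car4 (4.47), Lrrn4 (3.98), Upk3b (3.92), Tdo2 (3.84), Saa3 (3.52), Otor (3.23), Col6a5 (3.14), Chil4 (3.12), Ucma (2.74), Cnmd (2.73), Serpinb2 (2.64), Spp1 (2.38) and Chad (2.29). More positive in MyoF were Tgfbi (-2.17), Angptl7 (-2.36), Ngp (-3.18), S100a8 (-3.68), Retnlg (-4.25), Cd177 (-4.81), Cstdc5 (-4.84), Ly6g (-4.89), Stfa2 (-4.93) and Ifitm6 (-5.66). Glycam1, Otor and Ucma stood at 0, 0.103 and 0.53 FPKM in N-MF, where the log2(FPKM + 1) scale leaves little room for a fall, so their differences do not show that MF responded otherwise. The ratio of the M to the N mean of Ucma was 0.0503 in MF and 0.0489 in MyoF. Of the 17 lists that passed, 7 had a median difference of at least 0.5: mesothelial (2.06), MHC class II presentation (1.14), myofibroblast (0.75), NF-kappaB targets (0.63), matrix fibroblast of the Col14a1 type (-0.60), complement (-0.84) and neutrophil (-3.30). Of these 7, the call of the mesothelial list held (adjusted p = 0.015 with an estimated correlation). The other 6 lost it, with adjusted p = 0.105, 0.226, 0.0934, 0.214, 0.143 and 0.0539 with an estimated correlation in the order given.

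Of the tests below, those of a lower share of fibroblasts and those of the Tdo2 ratio were chosen after the result was seen; the tests on further gene sets were fixed before those sets were looked at. For neutrophil markers in M-MyoF, a further set of 12 genes that neutrophils share with other leukocytes had a median log2 fold change of 2.14. In this set 11 of 12 rose 2-fold or more, such as Ncf4 (3.33 ± 0.0574) and Coro1a (2.63 ± 0.101). Arhgdib (3.27 ± 0.0441) also rose in MF, from 13.4 to 156 FPKM against 278 in M-MyoF, so its rise was not particular to M-MyoF. Coro1a did not rise in MF (3.16 to 3.08 FPKM). The rise of the set is what RNA of neutrophils in the M-MyoF libraries would give. A lower share of fibroblasts would raise the markers of every other cell type alike, which did not happen, so it does not account for the rise alone. Against 5.22 for neutrophil genes, the highest median of 5 lists compared (endothelial, alveolar, airway, macrophage, T and NK cell) was 0.14 (endothelial), and mesothelial genes, outside these 5, had 0.65. Whether fibroblasts themselves express part of these genes in metastasis was not tested and stays open in bulk libraries.

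For mesothelial markers in M-MF, a further set of 8 mesothelial genes, 5 of them tested, had a median of 2.08, with 4 at 2-fold or more, such as Dmkn (4.25 ± 0.167) and Aldh1a2 (3.00 ± 0.0573), as RNA of mesothelial cells in these libraries would give. A lower share of fibroblasts does not account for it alone, since markers of other cell types did not rise alike. Against 3.82, the highest median of the 5 lists compared (endothelial, alveolar, airway, macrophage, T and NK cell) was 0.71 (airway epithelial) and the lowest -0.11 (macrophage and monocyte), while neutrophil genes, outside these 5, had 2.07. The mesothelial list's median log2(FPKM + 1) was 5.13 to 5.17 in the M-MF libraries and 4.93 to 4.98 in M-MyoF. A high level of these markers was therefore not particular to M-MF. That matrix fibroblasts took up mesothelial genes in metastasis, a biological explanation, was not tested.

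For Tdo2 in M-MF, the ratio of the M-MF to the M-MyoF mean was 3.67. Over the 13 neutrophil markers this ratio ran from 0.0089 (Ly6g) to 0.0805 (Mmp9), so RNA of neutrophils does not account for Tdo2 in M-MF. Over the 10 mesothelial markers it ran from 0.419 (Krt19) to 4.62 (Wt1) with a median of 1.33, a range that holds 3.67, so RNA of mesothelial cells cannot be told apart from expression by the fibroblasts themselves. The latter, the biological explanation the design offers, was not tested here, since no library separates the 2 cell types.

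Other splits of the same libraries were set against each real count. With 3 against 3 there are 10 splits, which cannot give a share under 0.05. The real split gave 10382, 10734, 10912 and 11320 genes for M-MF against N-MF, M-MyoF against N-MyoF, N-MF against N-MyoF and M-MF against M-MyoF, and the highest other split 0 in each, also among the 4 splits that part as many same-numbered pairs. For 2-fold changes the real counts of 1578, 1941, 2232 and 1804 also stood against 0. A split that mixes groups this far apart puts their difference into the spread between libraries, so gene counts of 0 follow from the design. They do not show what separate mice would give. For lists it was 21, 30, 23 and 24 against 12, 19, 17 and 18; in each case 1 split of 10, the real one, was as large. For the difference of effects, 2 of 100 splits drawn gave as many as 8566 genes (highest other 11369), 10 gave as many as 944 genes at 2-fold (highest other 4473) and 12 as many as 17 lists (highest other 22). The splits with as many genes besides the real one, 1 for all calls and 9 for 2-fold differences, were among 17 that kept or swapped whole the condition labels of 1 subgroup, and the rest gave 0. For lists, 4 of the 11 other splits as large were among those 17, and the rest reached up to 18 lists against the real 17. By the share of splits as large, the counts of lists and of 2-fold differences do not stand out from other groupings. Mixed splits put the metastasis effects into the spread between libraries. Those that keep or swap 1 subgroup whole carry its full effect into the contrast. Neither kind shows the count to be had if the effects did not differ.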

How the results depend on the processing

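Of 1028 values of named genes in a contrast, 986 kept their side of the threshold, and their direction if past it, under all 27 settings. A sign change of a value that passed in neither fit was not counted as a reversal. Under at least 1 setting 30 lost the call, 4 gained one and 13 reversed. Apart from the kynurenine pathway genes and subgroup markers, these genes were named for a large change or a small p in the same data. Their stability was therefore partly built in and does not stand for all genes. Over all genes in M-MF against M-MyoF, quantile normalization kept 8557 of 11320 calls. Reversed log2 values were, with a pseudocount of 0.1, Ido2 (0.83) and Slc7a11 (0.067) in the difference of effects. After rescaling to equal sums they were Col14a1 in the difference (0.075) and Pdgfra in M-MyoF against N-MyoF (-0.12). After median-ratio scaling they were Pdgfra there (-0.12), Got2 in N-MF against N-MyoF (0.083) and, in M-MF against M-MyoF, Afmid (0.21), Rpl4 (0.074), Rpl7 (0.028), Rpl3 (0.115), Ndrg1 (0.041) and Atp5a1 (0.001). After quantile normalization they were Pdgfra in M-MyoF against N-MyoF (-0.14), Afmid (0.045) and Kyat1 (0.041) in N-MF against N-MyoF, and Afmid in M-MF against M-MyoF (0.34). The cause was not tested.

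Counts in this paragraph follow the order M-MF against N-MF, M-MyoF against N-MyoF, difference, N-MF against N-MyoF, M-MF against M-MyoF. Requiring 2-fold left 1578, 1941, 944, 2232 and 1804 genes, by its construction fewer. With a pseudocount of 5, the 2-fold counts were 767, 1072, 456, 1107 and 861, and with 0.1 those of the comparisons 1, 3 and 5 were 2397, 1448 and 2768, since the pseudocount sets how far low genes can move. Lists passing camera with an estimated correlation were 6, 7, 1, 5 and 11, by fry 43, 46, 40, 45 and 45 with direction and 47 each without. Leaving out 1 library at a time gave 9999 to 10316, 10267 to 10698, 8111 to 8243, 10465 to 10866 and 10866 to 11284 genes. It gave 1538 to 1579, 1853 to 1941, 890 to 957, 2146 to 2232 and 1725 to 1804 at 2-fold, and 19 to 22, 28 to 31, 16 to 19, 22 to 23 and 24 to 25 lists. The correlation of the 2 effects was 0.735 with a pseudocount of 0.1, 0.719 with 5, 0.743 for genes at 5 FPKM or more, also as the filter of the whole fit, 0.748 without the libraries numbered 3, and 0.723 to 0.735 with 1 library left out; the cause was not tested.

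With the replicate number as a block, 10520, 10888, 8853, 11089 and 11462 genes passed in that order. Besides the list calls given with their results, the block ended that of alveolar epithelial genes in M-MyoF against N-MyoF (adjusted p = 0.0505). It ended those of the unfolded protein response in M-MF against N-MF (0.057) and M-MyoF against N-MyoF (0.0588), and of smooth muscle genes in the difference (0.0526). It brought glycolysis in M-MF against M-MyoF past the threshold (0.0352). With condition and number together as a block, endothelial and smooth muscle genes in the difference had 0.0519 and 0.061, and cholesterol synthesis and glycolysis in M-MF against M-MyoF 0.0487 each. Of the named genes, the number block brought Pdgfra in M-MyoF against N-MyoF past the threshold (0.06) and the joint block ended the call of Ido1 in N-MF against N-MyoF (-0.145). Among lists and named genes, the blocks changed no call besides those given here or with their results. Over all genes calls did change: in M-MF against N-MF the number block kept 10318 of the 10382 calls. Scaling changed more of them. Rescaling to equal sums kept 9512, median-ratio scaling 9224 and quantile normalization 8849. Depth is unknown, so no limit from read numbers can be given.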

Other observations

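Lipid-handling, growth factor and Wnt genes moved singly in both metastasis comparisons. The fatty acid binding proteins Fabp4 and Fabp5 rose in M-MF (4.12 ± 0.083 and 3.34 ± 0.0414) and in M-MyoF (2.31 ± 0.083 and 0.89 ± 0.0414). The lipofibroblast list had 4 of 10 genes up and 4 down in M-MF and did not pass (adjusted p = 0.822 and 0.996). Among growth factors, the EGF receptor ligand Areg rose in M-MF (2.25 ± 0.0787) and M-MyoF (2.55 ± 0.0787). Ereg (1.22 ± 0.0392) and the BMP antagonist Grem1 (1.85 ± 0.0698) rose in M-MF, and Bmp4 fell in both (-1.55 ± 0.0309 and -0.83 ± 0.0309); the list did not pass (adjusted p = 0.632 and 0.0817). The secreted Wnt antagonist Sfrp2 rose in both subgroups (1.32 ± 0.0322 and 1.36 ± 0.0322), Dkk2 fell in M-MF (-1.98 ± 0.0409) and Wif1 in M-MyoF (-1.66 ± 0.0356). The Wnt list had 4 genes up and 8 down in each subgroup (adjusted p = 0.0722 and 0.0726), and passed in M-MF without any 1 M-MF library (0.0282 to 0.0347) and without the libraries numbered 3 (0.0321). Prostaglandin synthesis rose in 9 of 10 genes in M-MyoF, Ptges by 1.68 ± 0.0229 and Pla2g4a by 2.19 ± 0.0328, and Hpgd, which degrades prostaglandins, fell (adjusted p = 0.0242; adjusted p = 0.0961 with an estimated correlation and 0.0808 at the stricter filter). Neutrophil markers had a median of 5.22 in the same libraries. The endothelial marker Lyve1 rose in M-MF (1.89 ± 0.0339) and M-MyoF (1.57 ± 0.0339), and Tek fell in both (-1.50 ± 0.0279 and -0.90 ± 0.0279). The endothelial list had no call (adjusted p = 0.134 and 0.967; 0.0312 in M-MF without the expression filter).

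The unfolded protein response rose in 12 of 16 genes in each subgroup, with the disulphide isomerases Pdia4 (1.53 ± 0.0181 in M-MF) and Pdia6 (1.33 ± 0.0173 in M-MF and 1.45 ± 0.0173 in M-MyoF). Dnajb9, Atf4, Ddit3 and Herpud1, chosen after their values were seen, fell in both. The set had adjusted p = 0.0423 and 0.0484, adjusted p = 0.124 and 0.101 with an estimated correlation. It had 0.0801 and 0.0995 at the stricter filter, 0.0586 and 0.0765 with only the compared groups in the fit, 0.057 and 0.0588 with the replicate number as a block and 0.0589 and 0.0645 without the libraries numbered 3. Leaving out 1 library gave 0.0514 in M-MF without N-MyoF replicate 2, and between 0.0521 and 0.0571 in M-MyoF without any 1 of the N-MF, N-MyoF or M-MF libraries. Fibrillar and network collagens fell in 10 of 17 cases in M-MyoF, Col10a1 by -2.26 ± 0.0695 and Col14a1 by -0.77 ± 0.0187, and rose in 4. The call (adjusted p = 0.0242) was lost elsewhere, with adjusted p = 0.325 with an estimated correlation, 0.0721 at the stricter filter, 0.0937 without the libraries numbered 3, and 0.0894, 0.0945 and 0.0629 without N-MyoF replicate 1, 2 or 3. Adjusted over the list alone, 14 instead of 12 Wnt genes changed in M-MF and the other counts in these paragraphs were the same.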
